A study of Mus musculus with 2 samples.

How the data were processed

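DNase I hypersensitivity sequencing was measured in the cerebellum of female B6CASTF1/J mice at 14 days of age, in 2 biological replicates of 1 group. Per the labels, each replicate is a separate collection of 3 females, both replicates carry the same donor record, and both list the same pair of sequencing instruments. The labels name no batch, date or control sample. The 4 files used per replicate were a longer and a shorter list of peaks, a list of footprints and a list of stretches with a false discovery rate.

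What the authors did is known only from the labels and from the text file deposited with each sample. Per the labels, coordinates are on the mm10 assembly. Per the deposited text files, each library was aligned and processed on its own, and the peaks and footprints derive from filtered alignments of that library. The peak caller, the footprint caller and their versions are not given in the sources used here. The peak strength is a signal value in the deposited peak files, and its scale is not stated. The values were checked to be whole multiples of 1 step per library: 100% of the values up to 300 steps lay within 0.1 step of a whole multiple. The step was 0.00724 in replicate 1 and 0.00360 in replicate 2, as DNase I cleavage counts divided by 1 factor per library would give. The deposited stretches carry a false discovery rate (a q-value) between 0 and 0.05, and the deposited footprints carry the same false discovery rate, 0.01, as a p-value column in every row. Of the longer peak lists, all but 1 of 183803 peaks of replicate 1 and all of the 257076 peaks of replicate 2 touched a stretch at a rate of 0.05 or below. All peaks of the shorter lists touched a stretch at 0.001 or below. Read totals are not given in the sources used here, so depth is known only through the step. Precision is limited by the use of 2 replicates.

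Genes came from GENCODE release M21, and sequence came from the RefSeq copy of GRCm38, whose chromosome lengths and coordinates are those of mm10. Peaks of both replicates that overlapped by at least 1 base were merged into regions. A region counted as shared when it held a peak of each replicate, and its strength in a replicate was that of its strongest peak. A region within 1 kb of an annotated transcript start counted as lying at a start, and all others counted as distal. The rest were put into exon, intron or intergenic classes by their midpoint and set beside 1000000 random positions. Of the protein-coding genes off chromosome Y, 21644 had a symbol and were tested. A gene had an accessible start when a shared region lay within 1 kb of one of its starts, even if the peak of 1 replicate in that region lay farther off. Each distal shared region went to the gene with the nearest start. The stretch of genome nearest to a gene was called its territory.

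The chance level of overlap between replicates came from moving 1 list in 10 steps of 1 Mb around each chromosome. For footprints it also came from 10 random placements within the peak that held each footprint. Cell type lists of 365 gene names in 25 lists were written before the data were examined, as were all tests, thresholds and alternatives not said to be added. Of these names 364 matched a tested gene; the erythroid gene Ahsp did not. The lists are not independent. Tbr1, Zic1, Zic2, Atoh1, Pax2, Tal1, Otx2, Olig2 and Sox10 each stand in more than 1 list, and several genes are expressed by more than 1 cell type. The share of accessible starts in each list was compared with that of all other genes by two-sided Fisher's exact tests, with exact Clopper-Pearson 95% intervals. Distal regions per gene were compared with 10000 random lists of the same size, matched on 10 classes of territory size, by two-sided permutation tests. The smallest p these permutations can give is 0.0002. All p-values of lists were adjusted by the Benjamini-Hochberg method over the 25 lists, with a threshold of 0.05. In these tests genes are the units, not animals, and no test across animals was possible with 1 group. Binding was not measured. Instead, 22 consensus sequences were counted in footprint bases inside peaks against all other peak bases of the same replicate. Both were pooled over peaks, so the other bases include those of peaks without a footprint. The ratios therefore do not separate footprints from the kind of peak that holds them. Rate ratios have 95% counting intervals, and up to 20 permuted consensuses were counted for most consensuses. Intervals cover counting error only.

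Genes are named by a fixed rule, and not every gene it picks is named. From each list come up to 3 members with the strongest shared start region and up to 3 members, in alphabetical order, with no start peak in either replicate. Beyond the lists come the 10 genes with the most distal shared regions, the 10 with the highest mean percentile of a start peak, and the genes nearest the 10 strongest regions of each replicate without a peak in the other. Other genes named were chosen after their values were seen. The distance from each named region to the nearest start of another gene was also added then.

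The list tests were tested on simulated data with the 21644 real genes, in 20 runs for each kind of list of 15 genes. Lists drawn with few accessible starts were called in 16 of 20 runs. Lists of 15 genes with every start accessible were called in 0 of 20 runs when they were the only unusual list, so a higher call of a list of that size depends on other lists also being far from the background. Lists drawn at random were called in 0 of 20 runs. Lists with 2-fold and 3-fold as many distal regions were called in 8 and 14 of 20 runs, and lists with 1-fold in 0 of 20. In simulated sequence, a consensus planted at a rate ratio of 5 was recovered at 4.93.

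The alternatives were start windows of 500 and 2500 bases, the stronger 50% of each list, reciprocal overlap of at least 50%, lists of equal length, a background matched on CpG content within 500 bases of the start, distal regions capped at 100 kb, footprints moved by 50 bases as background, footprints found in both replicates, density per gene, and each replicate left out. Added after the data were seen were the authors' shorter lists, peaks within 100 bases counted as shared, and lists without their top member. Families of genes by symbol prefix, with at least 25 genes each, the permuted consensuses, the distances of regions found in one replicate to peaks of the other, and the comparison of list strengths between replicates were also added then. Chromosome Y regions were compared with the whole assembly with BLAST 2.17.0 at 90% identity or more over 80% of their length. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9. Chromosome M and unplaced sequences were left out, and footprints could not be ranked because they carry no score. The parental alleles of the hybrid were not analysed here, because the files hold no allele information.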

Results

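DNase I hypersensitivity sequencing maps the chromatin that the enzyme DNase I can reach, which is mostly promoters, enhancers and insulators. It was applied to the cerebellum of female B6CASTF1/J mice, an F1 hybrid of a pair of inbred strains, at 14 days of age. At this age granule neurons, the most numerous cerebellar neurons, are still being produced by dividing progenitors. The series holds 1 group of 2 biological replicates, each labelled as 3 females, and no control, so nothing was compared between groups. The labels state no question. Replicate 1 held 183803 peaks over 32.4 Mb and 460680 footprints, and replicate 2 held 257076 peaks over 46.6 Mb and 729279 footprints. A footprint is a short stretch inside accessible chromatin called as protected from cleavage, as a bound protein that shields the DNA would leave it. Binding was not measured, and the sequence preference of DNase I itself was not examined. The median peak spanned 164 bases in replicate 1 and 180 in replicate 2. Its strength was 108 steps of the replicate's own scale in replicate 1 and 135 in replicate 2. If a step is 1 cleavage and both libraries were scaled to the same total, replicate 2 held 2.01 times as many cleavages as replicate 1.

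The same accessible regions recurred in both replicates, and the strongest ones almost without exception. Of the peaks of replicate 1, 87.1% overlapped a peak of replicate 2, and 62.3% of the peaks of replicate 2 overlapped one of replicate 1. Lists moved along the chromosomes overlapped at 3.96% and 2.85% on average over 10 shifts. Replicate 2 has the longer list. With both lists cut by strength to equal length, 76.0% of the peaks of each replicate overlapped one of the other. Among the strongest 10% of peaks the share was 99.4% in replicate 1 and 99.2% in replicate 2, against 53.7% and 17.7% among the weakest 10%. Merging gave 276819 regions, of which 157255 (56.8%) held a peak of each replicate, 23614 a peak of replicate 1 alone and 95950 a peak of replicate 2 alone. Across the shared regions, which are not independent replicates, strength had a Spearman rho of 0.905 between the replicates. The median log2 ratio of replicate 2 over replicate 1 was -0.22.

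**Figure D1:**
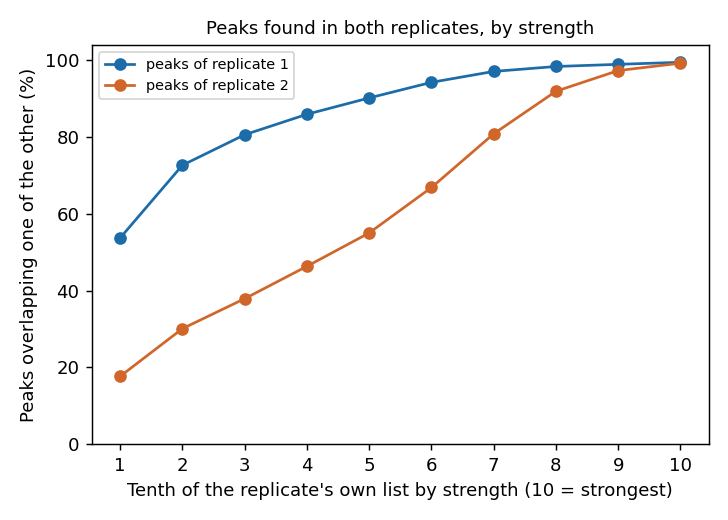
Percentage of peaks in each replicate that overlap a peak of the other (vertical axis), in 10 equal classes of the replicate's own peak strength (horizontal axis, strongest at 10). The share climbed from 53.7% to 99.4% in replicate 1 and from 17.7% to 99.2% in replicate 2.

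Strong regions found in one replicate alone lay mostly beside a peak of the other. Among the strongest 10% of replicate 1, 98 of 18273 regions (0.536%) had no peak in replicate 2, and 199 of 25556 (0.779%) of replicate 2 had none in replicate 1. Of these, 60 and 138 lay within 100 bases of a peak of the other replicate, and 98 and 197 touched its stretches at a false discovery rate of 0.05 or below. Hip1, which encodes an endocytic adaptor that interacts with huntingtin, had one such region in each replicate. They abutted on chromosome 5, at 135545321 to 135545380 in replicate 1 (strength 25.6) and 135545241 to 135545320 in replicate 2 (strength 12.5). Others of replicate 1 lay nearest Ngdn, Prss52, Tmem87b, Eloc, Mon1b, Hcfc1r1, Pum2 and Mpc1. Those of replicate 2 lay nearest Evi5l, Hnrnph1, Gatad2b, Rngtt, Dcaf11, Rbfox3, Slc22a12, Rbpj and Nek2. The region in an intron of Rbfox3, which encodes the neuronal nuclear antigen NeuN, was at 118750841 to 118751020 on chromosome 11 (strength 13.8), 21 bases from a peak of replicate 1.

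Accessible chromatin was concentrated at gene starts. Of the shared regions, 34811 (22.1%) lay within 1 kb of an annotated transcript start, against 4.73% of random positions, a 4.68-fold excess. Exons held 5.81% of the shared regions (2.03-fold), introns 40.3% (1.00-fold) and intergenic sequence 31.8% (0.608-fold). Of the 16253 regions in the strongest 10% of both replicates, 62.3% lay at starts. Regions of replicate 1 alone lay at starts in 14.8% of cases and those of replicate 2 alone in 12.4%. The strongest starts were those of Hjurp (strength 64.0 ± 12.2, SD, n = 2), which encodes a chaperone of centromeric histones, Bahcc1 (62.3 ± 19.2) and Dynlt1b (62.5 ± 25.3), which encodes a dynein light chain. Among the next by mean percentile were Ankhd1, Rab40c, Fzr1 and Sde2, and Rragc with 4930535I16Rik, whose starts share a region. Of 21644 protein-coding genes, 14693 (67.9%) had an accessible start, that is, a shared region within 1 kb of it.

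Genes of granule neurons and of their progenitors had accessible starts throughout. All 20 listed granule neuron genes (95% interval 83.2 to 100%) and all 15 progenitor genes (78.2 to 100%) were accessible in both replicates, against 67.9% of the other genes. The strongest granule neuron start was that of Tiam1, which encodes an activator of the GTPase Rac, on chromosome 16 at 90144201 to 90144380 (strength 27.6 ± 7.47, SD, n = 2). Cbln3, which encodes a secreted partner of cerebellin (23.1 ± 8.89), and Neurod1, which encodes a neuronal differentiation factor (22.7 ± 8.21), followed. The progenitor genes Mycn (7.88 ± 0.636), Ptch1 (7.60 ± 3.12) and Mki67 (7.50 ± 1.88) encode a growth regulator, the Sonic hedgehog receptor and a proliferation antigen. All 16 general neuronal genes were accessible, with Vamp2 (14.3 ± 3.55) and Tubb3 (11.4 ± 5.16) among the strongest, as were all 16 housekeeping genes, led by Eef2 (34.7 ± 3.69), Rplp0 (27.1 ± 0.957) and Ywhaz (23.7 ± 11.8). Two-sided Fisher's exact tests over genes called these 4 of 25 lists higher, with adjusted p = 0.00222 for granule neurons, 0.00969 for progenitors and 0.00642 for each of the others. Against 10000 random lists matched on CpG content, permutation tests gave adjusted p = 0.0150 for each granule list. The same tests gave 0.175 for general neuronal genes and 1 for housekeeping genes, and both calls ended. Their random lists averaged 84.9% and 95.9%. With 16 of 16 genes accessible neither list could have scored higher, so this test could not call them. Their lost calls therefore do not show that CpG content accounts for the accessible starts. In the list of replicate 2 alone, 8 lists were higher, adding Bergmann glia, interneurons, early patterning and meninges.

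**Figure D2:**
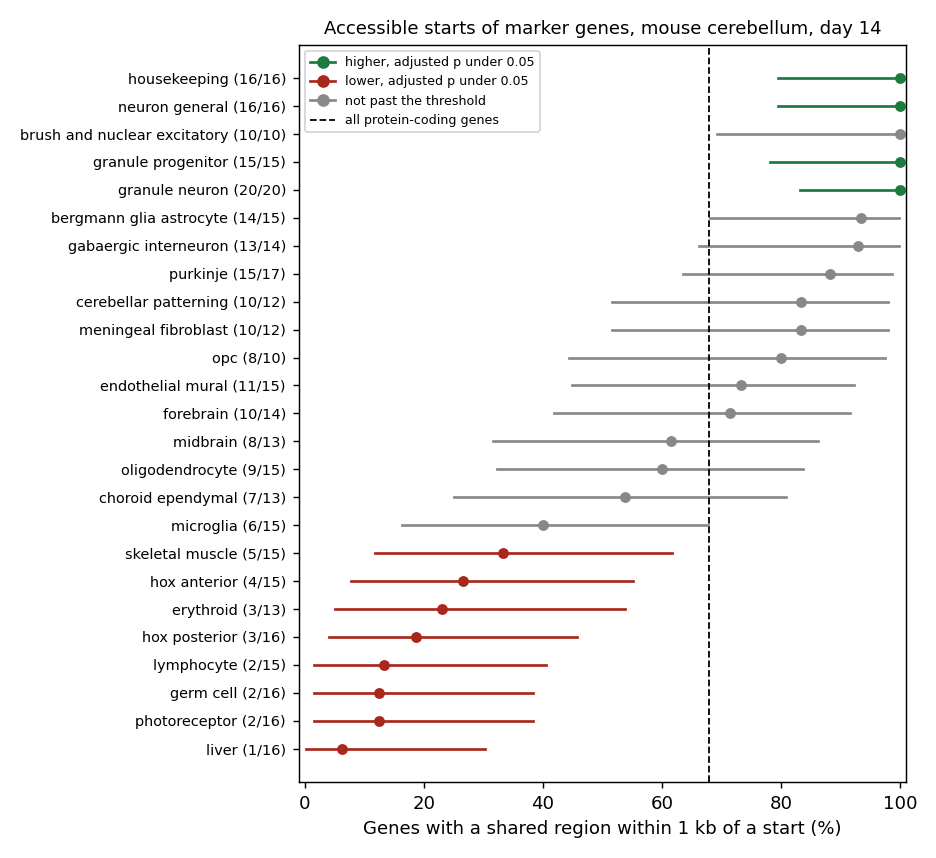
Percentage of the genes of each list with a shared region within 1 kb of a start (points, with exact 95% intervals as bars; genes accessible over genes listed in brackets). The dashed line marks all 21644 protein-coding genes at 67.9%; granule neuron genes stand at 20 of 20 and liver genes at 1 of 16.

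Around Neurod1 the strongest peak of each replicate lay at the gene's own start, at 79456751 on chromosome 2 (mm10). That of replicate 2, at 79456601 to 79456980, covered the start (strength 16.9), and that of replicate 1, at 79456761 to 79456820, began 10 bases upstream of it (strength 28.5). Both peaks also cover position 79456785, where the annotated body of Cerkl begins on the same strand, so they cannot be assigned to Neurod1 alone. Within 30 kb of the gene (ENSMUSG00000034701.9) there were 16 peaks and 46 footprints in replicate 1, and 26 peaks and 103 footprints in replicate 2.

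**Figure D3:**
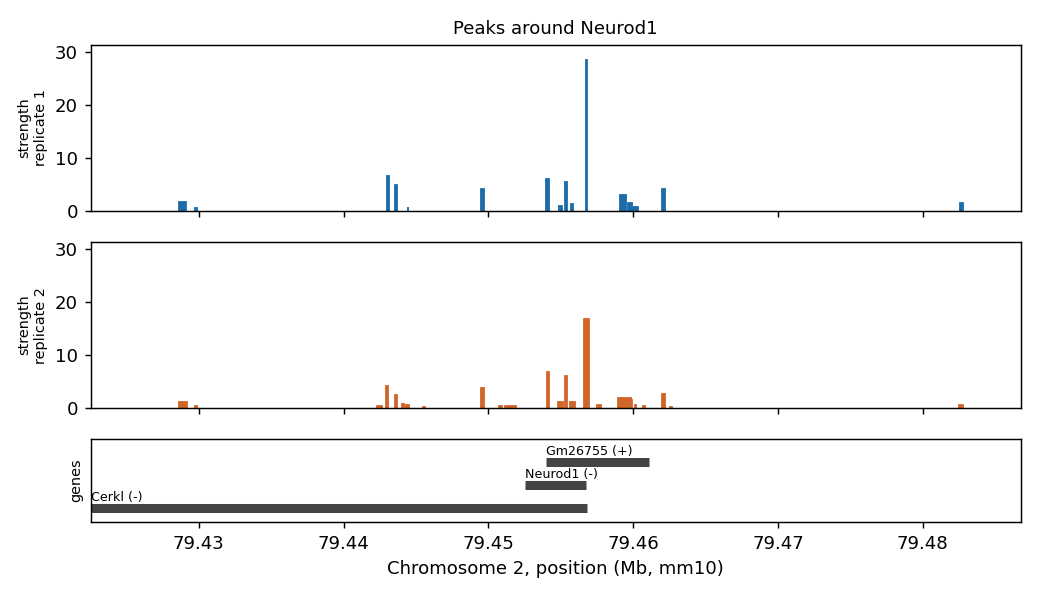
Peak strength (vertical axis, deposited signal, scale not stated) along chromosome 2 in Mb (horizontal axis) from 30 kb before to 30 kb after Neurod1, with annotated genes and their strands in the lowest panel. The highest peak, 28.5 in replicate 1 and 16.9 in replicate 2, stands within 10 bases of the Neurod1 start and covers the upstream end of Cerkl.

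Starts of other cerebellar cell types were mostly accessible too, although none of these lists passed the test with the settings fixed as main. Among excitatory unipolar brush and nuclear neuron genes 10 of 10 were accessible, with Slc17a6 (6.81 ± 1.54, SD, n = 2), which encodes a glutamate transporter, strongest and Eomes also among the strongest. Among GABAergic interneuron genes 13 of 14 were, led by Ptprk, Pvalb (2.5 ± 0.0149), which encodes parvalbumin, and Kit; Tfap2b was the exception. Among Purkinje cell genes 15 of 17 were, led by Itpr1, an intracellular calcium channel gene (14.4 ± 5.59), Lhx1 and Pcp4; Pcp2 had no start peak in either replicate and Ppp1r17 lacked a shared one. Bergmann glia and astrocyte genes had 14 of 15, led by the radial glial gene Fabp7 (10.3 ± 1.94), Sox9 and Nfia, with Aldh1l1 the exception. Of the early patterning genes 10 of 12 were accessible, led by En2 (16.4 ± 4.22), a midbrain-hindbrain boundary factor, then Zic1 (12 ± 5.15) and Zic2. Adjusted p in Fisher's exact tests was 0.0653 for brush and nuclear neurons and 0.0755 each for interneurons and Bergmann glia. It was 0.169 for Purkinje cells and 0.465 for patterning. The brush and nuclear list was already at 10 of 10, so with 10 genes it could not pass beside these other lists. Its result is therefore no difference from the granule lists. Under alternatives, Fisher's exact tests called brush and nuclear neurons (adjusted p = 0.0352) and Bergmann glia (0.0452) higher with a window of 500 bases, Bergmann glia also in the authors' shorter lists (0.0282), and Purkinje cells in the list of replicate 1 alone (0.0400). Against random lists matched on CpG content, permutation tests called none of these lists (adjusted p of 0.436 or more). At 10 of 10 the brush and nuclear list could not have been called there either. Those random lists averaged 94.2% for interneurons and 90.2% for patterning, above the observed 92.9% and 83.3%. They averaged 83.7% for Purkinje cells, 89.6% for brush and nuclear neurons and 80.2% for Bergmann glia, below the observed 88.2%, 100% and 93.3%.

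Lists of oligodendrocytes, vessels and borders of the brain did not pass the test in either direction, and microglial genes had the lowest share among them. Oligodendrocyte genes were accessible in 9 of 15 cases (adjusted p = 0.661, Fisher's exact test), with the lineage factors Olig1 (2.67 ± 0.307, SD, n = 2) and Myrf and the myelin lipid enzyme gene Ugt8a strongest, while the myelin genes Mobp, Mog and Opalin had no start peak in either replicate. Oligodendrocyte precursor genes had 8 of 10 (0.616), led by C1ql1, Pdgfra and Lhfpl3, with none at Neu4. Endothelial and mural genes had 11 of 15 (0.819), led by Vtn, Kdr and Flt1, with no peak at Cdh5, Ly6c1 or Pecam1. Meningeal fibroblast genes had 10 of 12 (0.465), led by the collagen gene Col1a1 (7.2 ± 4.88), Foxc2 and Foxc1. Choroid plexus and ependymal genes had 7 of 13 (0.465), led by the cilium genes Rsph1 (23.2 ± 3.98) and Foxj1 (11 ± 0.399) and by Ccdc153, while Sostdc1, Tmem212 and Ttr, the transthyretin gene of choroid plexus, had none. Microglial genes had 6 of 15 (0.0521), with Tmem119 among the strongest and no start peak at C1qa, C1qb or Cx3cr1. The microglial list was lower past the threshold in all 6 alternatives run with Fisher's exact test, but had adjusted p = 1 in the permutation test with CpG-matched lists. In the stronger 50% of each list, the endothelial and meningeal lists were lower too (adjusted p = 0.0247 and 0.0255, Fisher's exact test).

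Genes of other tissues and of other body levels had mostly closed starts. Liver genes were accessible in 1 of 16 cases (adjusted p = 1.1e-05, two-sided Fisher's exact test), the exception being the apolipoprotein gene Apob, and Ahsg, Alb and Cps1 had no peak. Photoreceptor genes had 2 of 16 (6.05e-05), Rom1 and Cngb1, with none at Cnga1, Gnat2 or Nr2e3. Germ cell genes had 2 of 16 (6.05e-05), Dazl (12.4 ± 4.45, SD, n = 2) and Mael, with none at Ddx4, Gdf9 or Nobox. Lymphocyte genes had 2 of 15 (0.000124), Rag1 and Lck, with none at Cd3d or Cd3g. Erythroid genes had 3 of 13 (0.00398), among them Epor and Tal1, with none at Alas2, Gata1 or Hba-a1. Skeletal muscle genes had 5 of 15 (0.0194), led by Actn3, Mylpf and Tnnc2, with none at Acta1, Cacng1 or Ckm. The regions at several of these starts lay closer to or beside another gene: that of Actn3 covered a start of Zdhhc24, that of Mylpf ended 113 bases from a start of Tbc1d10b, and that of Rom1 ended 12 bases from one of Eml3. With CpG-matched random lists the calls of 5 lists ended, with permutation adjusted p = 0.0617 for liver, 0.0594 for photoreceptors, 0.635 for skeletal muscle, 0.723 for lymphocytes and 1 for erythroid genes. The CpG-matched random lists averaged 25.2% for lymphocyte and 25.1% for erythroid genes, which left little room for a lower call. The skeletal muscle call also ended in the list of replicate 2 alone (adjusted p = 0.459, Fisher's exact test). It ended too with a window of 2500 bases (0.222, the same test).

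Hox genes, which set position along the body axis behind the cerebellum, were mostly closed in spite of CpG-rich starts. Of the posterior Hox genes 3 of 16 were accessible (adjusted p = 0.000373, two-sided Fisher's exact test), Hoxc10, Hoxa10 and Hoxb9, and Hoxa11, Hoxb13 and Hoxc11 were among 10 with no start peak. Of the anterior Hox genes 4 of 15 were (0.00398), with Hoxb5 (1.39 ± 0.960, SD, n = 2) and Hoxc5 strongest and no peak at Hoxb1, Hoxb3 or Hoxb4. Midbrain genes had 8 of 13, with Otx1 and Pou4f1 among the strongest and none at Gata2 or Th, the gene of the rate-limiting enzyme of dopamine synthesis. Forebrain genes had 10 of 14, with Bcl11b and Tbr1 among the strongest and none at Fezf2, a cortical projection neuron factor. Tbr1 also stands in the list of cerebellar brush and nuclear neurons. Neither of these passed Fisher's exact test (adjusted p = 0.819 and 1). Against random lists with the same CpG content, permutation tests called both Hox lists and the germ cell list lower (adjusted p = 0.0017 each) and also the midbrain list, whose random lists averaged 89.4%, and the forebrain list (96.2%), with adjusted p = 0.0150 and 0.0157. The anterior Hox call ended in the list of replicate 2 alone, where 9 of 15 genes were accessible (adjusted p = 0.459, Fisher's exact test). Hox genes lie side by side in clusters, but both kinds of test count each gene as independent. The p-values of the Hox lists may therefore be too small.

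Granule neuron genes and general neuronal genes were surrounded by more distal accessible regions than other genes with as much territory. Granule neuron genes had a mean of 27.4 distal shared regions per gene, against 13 in random lists (2.10-fold; 95% of lists between 8.10 and 19.2). General neuronal genes had 31.3, against 13 (2.41-fold; 7.63 to 20). Tiam1 had 52, Rbfox3 74 and Etv1 47, the last pair chosen after their values were seen. Of all genes the most distal regions lay around Rbfox1 (145), a neuronal splicing regulator, the cell adhesion gene Ntm (137), Auts2 (136), Celf4 (136), Pde4d (109), Cdh4 (108), Zmiz1 (108), Zfp608 (99), Rora (98), a nuclear receptor gene needed by Purkinje cells, and Opcml (98). The territory of Rbfox1 spanned 2022 kb and that of Zmiz1 602 kb. In the two-sided permutation tests of these counts both lists had p = 0.0002, the smallest the permutations can give, and adjusted p = 0.0025. In the same permutation tests, the general neuronal list without Rbfox1 had 23.7 regions per gene and adjusted p = 0.0525, which ended its call, and without Rbfox3 the granule neuron list kept 24.9 and 0.045. The random lists kept their own top members, so p rises in part by construction. Distal regions of the granule neuron list were weaker in replicate 2. Their mean log2 ratio to replicate 1, centred on all distal regions, was -0.21, against 0.01 in random lists. The general neuronal list, at -0.131, lay just below 95% of its random lists (-0.129 to 0.264). Progenitors, at -0.125, lay just inside theirs (-0.132 to 0.225). These ranges were not adjusted over the 25 lists, and each side is 1 library.

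No other list passed the distal test. Granule progenitor genes had 18.3 regions per gene against 11.2 in random lists, and patterning genes 18.3 against 10.9 (adjusted p = 0.179 each, permutation tests). Purkinje cell genes had 20.7 against 15.2 (0.301) and Bergmann glia genes 18.0 against 12.9 (0.344). Posterior Hox genes had 0.375 against 1.47 (0.115), and anterior Hox genes 0.667 against 1.61 (0.262). The remaining lists had adjusted p from 0.262 to 0.985 in the same permutation tests. Lists of this size with a simulated 2-fold excess were called in 8 of 20 runs, so excesses of this size were often not detectable. Lists with too few distal regions were not simulated.

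Footprints recurred between the replicates more often than after random placement within their peaks. Of the footprints of replicate 1, 73.7% overlapped one of replicate 2, and 44.4% of those of replicate 2 overlapped one of replicate 1, against 0.995% and 0.625% after shifts. Among footprints inside peaks the shares were 73.0% and 44.3%, against 50.7% and 31.9% when each was placed at random within its peak. The placement was uniform within the peak and kept no preference for position or base content. It therefore cannot tell recurring protected sites from such preferences shared by both libraries. Most peaks held a footprint, 79.0% in replicate 1 and 84.4% in replicate 2, and footprints had a GC content of 62.8% and 60.5% against 54.5% and 53.1% in the other peak bases.

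Footprints were rich in the sequences of ubiquitous promoter factors, of the insulator protein CTCF and of several neural factors. The consensus of NRF1, an activator of mitochondrial and housekeeping genes, was 51.4 times as frequent in footprints as in the other peak bases in replicate 1 (95% interval 36.8 to 71.6) and 41.1 times in replicate 2 (29.98 to 56.5). That of CTCF was enriched 19.8-fold (18.6 to 21.1) and 28.5-fold (26.7 to 30.5), on 5188 and 7155 sites, against 1.95 and 1.93 for permuted consensuses. NFI, a family that drives late granule neuron maturation and gliogenesis, gave 8.53 (6.85 to 10.6) and 25.3 (19.9 to 32.0), and ZIC, a family of granule cell regulators, 4.03 and 5.54. CREB gave 11.1 and 6.80, SP and KLF factors 8.06 and 8.25, YY1 6.31 and 4.82, RFX 5.03 and 3.18, ETS 3.16 and 2.29, and NF-Y 1.53 and 1.47. The E-box CAGATG, which NEUROD1 and ATOH1 can bind, gave 1.57 and 1.26, against 0.752 and 0.798 for its permuted forms, and CAGCTG gave 1.58 and 1.51. The consensus of the neuronal repressor REST lay above 1 in replicate 2 (7.68, 4.65 to 12.7) but not beyond counting error in replicate 1 (1.97, 0.863 to 4.50, on 8 sites). Consensuses of AP-1, MEF2, SOX, ROR, GATA and homeodomain factors, most of them rich in A and T, lay below 1 in both replicates, from 0.311 to 0.632, and so did the medians of their permuted forms, from 0.398 to 0.644. The ratios of YY1, ETS, NF-Y and CAGCTG lay within the range of their own permuted forms in both replicates, which reached 18.7, 3.20, 5.65 and 3.34 in replicate 1, and SP, KLF and REST consensuses had too few permuted forms to compare. With footprints moved by 50 bases as background, NFI gave 43.3 and 51.5, CTCF 35.7 and 38.4, and NRF1 34.2 and 27.9. ZIC rose to 6.00 and 7.01 and REST to 9.19 and 11.4. CREB gave 11.8 and 5.33, RFX 4.84 and 2.55, YY1 3.57 and 2.47, and ETS 1.71 and 1.41. NF-Y fell close to 1, at 1.13 (95% interval 1.01 to 1.26) and 1.15 (1.04 to 1.27). This background held only 6 and 10 sites of NFI and 1 and 4 of REST. In replicate 1 the 95% interval was 19.2 to 97.4 for NFI and 1.15 to 73.5 for REST. Of 22 consensuses, 12 lay above 1 and 6 below 1 in both replicates, and those of PU.1, HNF1 and p53 had at most 3 sites in the footprints of a replicate.

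**Figure D4:**
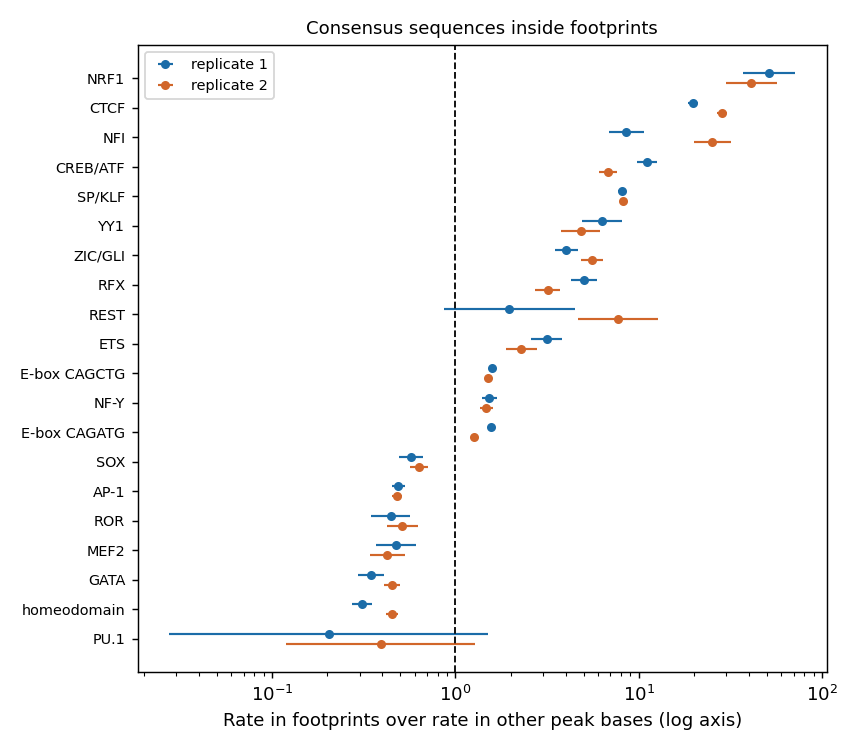
Rate of each consensus in footprints over its rate in all other peak bases of that replicate (horizontal log axis), with 95% counting intervals as bars. NRF1 lies highest with this background, at 51.4 and 41.1, and the consensuses of AP-1, MEF2, SOX, ROR, GATA and homeodomain factors lie below 1.

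Chromosome X of these female animals carried fewer peaks than the autosomes. It held 4599 peaks in replicate 1 and 6717 in replicate 2, 26.9 and 39.3 per Mb, against 72.8 and 102 per Mb on autosomes, a ratio of 0.378 ± 0.0119 (SD, n = 2). Per protein-coding gene the ratio was 0.573 ± 0.0181. Chromosome 11 was the densest, with 105 and 149 peaks per Mb, and chromosome 3 the sparsest autosome, at 0.779 and 0.772 of the autosomal density. One X chromosome is inactive in each female cell, and the files do not tell the parental copies apart.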

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

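The tests of the chromosome Y regions below were planned, and none was chosen after the result was seen.

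Peaks on chromosome Y appeared in libraries labelled as female, outside the main comparisons. Replicate 1 held 35 and replicate 2 held 79, which merged into 81 regions, 23 of them shared, and no control sample sets a background. Male tissue in the pools is argued against: there were 0 peaks within 1 kb of the starts of the broadly expressed Y genes Ddx3y, Eif2s3y, Kdm5d and Uty in either replicate. Of the Y regions, 72.8% have a copy on another chromosome at 90% identity or more, against 1.23% of as many random autosomal regions, so reads from shared sequence may account for most of them. The regions without such a copy stay unexplained, and no biological explanation was tested. Among them are 10 of the 23 shared regions, which reached percentile 73.2 of strength in replicate 1 and 72.6 in replicate 2. Except the region that starts at 10640921, these shared regions lie together between 90723701 and 90744200 on chromosome Y.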

How the results depend on the processing

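The alternatives chosen after the data were seen were the authors' shorter lists, peaks within 100 bases counted as shared, and lists without their top member. Of the alternative values of the main results, 54 stayed within the spread or within 1.5 times a count and 25 moved. For the shares of shared peaks the spread was the SD between the replicates. It is wide, so lists of equal length, at 76.0% in each replicate, counted as staying. Of those of lists and consensuses, 398 kept their side of the threshold, 18 passed it, 11 no longer did and 3 reversed. With the stronger 50% of each list, peaks numbered 91901 and 128538 over 18.5 and 26.4 Mb, and in the shorter lists 115292 and 159095 over 20.8 and 29.3 Mb, by construction. The Spearman rank correlation of strength was 0.903 with reciprocal overlap and 0.830 in the stronger 50% of both lists. The share of shared regions at starts was 17.3% at 500 bases, 29.7% at 2500 bases, 29.7% in the stronger 50%, 27.1% in the shorter lists and 18.5 to 21.3% with a replicate left out. Lists called higher at starts numbered 2 with CpG matching and 5 to 8 with a replicate left out, 8 without replicate 1, and lists called lower 5 with CpG matching. Endothelial (-34.3 points) and meningeal genes (-36.0) fell below the other genes in the stronger 50%, and forebrain genes (-24.7) with CpG matching. Lists called higher for distal regions numbered 1 without the top member, in part by construction, because the random lists kept theirs. Reciprocal overlap left 51.1% of footprints of replicate 1 shared. The X ratio was 0.260 in the stronger 50%, 0.356 in the shorter lists and 0.573 per gene. Of the 10 genes with the most distal regions, 5 stayed in the stronger 50% and 3 within 100 kb. Except where construction is named, the cause was not tested. Alternatives that rank footprints by score were not run, because the footprints carry none. Read totals are not given in the sources used here; of the weakest 10% of peaks, 53.7% in replicate 1 and 17.7% in replicate 2 were shared.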

Other observations

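All family tests below, and the tests of the granule neuron list between replicates, were chosen after the result was seen; the depth test was planned.

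Large gene families differed in how often their starts were accessible. Of 75 symbol prefixes with at least 25 genes, 40 were higher and 21 lower than other genes (two-sided Fisher's exact tests over genes, adjusted over the 75). These tests were not matched on CpG content, which ended the calls of several cell type lists. They also count the members of a family as independent. How well reads can be placed in members of similar sequence was not examined. Olfactory receptor genes (Olfr) had accessible starts in 53 of 1133 cases (4.68%), vomeronasal receptor genes (Vmn) in 7 of 330, taste receptor genes (Tas) in 1 of 38, the reproductive homeobox cluster (Rhox) in 1 of 34, prolactin genes (Prl) in 1 of 26 and beta-defensin genes (Defb) in 5 of 42. Keratin genes (Krt) had 10 of 53 and cytochrome P450 genes (Cyp) 28 of 100. All 49 Mrpl and all 29 Mrps genes, which encode mitochondrial ribosomal proteins, were accessible, as were all 30 Med genes of the Mediator complex, all 28 Polr genes of RNA polymerases and all 35 Vps genes of vesicle sorting. Zinc finger genes (Zfp) had 348 of 394 (88.3%) and Rab GTPase genes 66 of 69, while solute carriers (Slc, 268 of 371) did not pass the exact test (adjusted p = 0.0852). For distal regions 1 prefix was higher, Zbtb, a family of transcriptional repressors, with 7.78 per gene against 4.76 (adjusted p = 0.047, permutation test), and 14 were lower, among them the secretoglobins (Scgb, 0.5 against 5.91, adjusted p = 0.0017).

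Distal regions of granule neuron genes were weaker in replicate 2 than in replicate 1, relative to other distal regions. The mean log2 ratio of the list was -0.21, against 0.01 in random lists with as many and as strong regions (95% of lists between -0.12 and 0.16), but it was not alone: the general neuronal list stood at -0.13 (percentile 2.27 of its random lists) while granule progenitors, at -0.13 (2.87), lay inside their range. GC content and peak strength as the whole cause are argued against, because after centring within classes of both the list still lay -0.25 from its random lists. A lower share of granule neurons in replicate 2 may contribute, but 6 of the 10 other cerebellar lists lay above the middle of their random lists, at percentiles from 23.4 to 95.3, so it cannot be told apart from a difference in the state of these neurons or of neurons at large; after the same centring the general neuronal list stood at percentile 1.85 and progenitors at 8.72. With 1 library a side, no test across animals was possible, and no biological explanation was tested.

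Replicate 2 held 95950 regions that replicate 1 lacked. At the depth of replicate 1, taking the strength as a scaled count, 44.0% of them would be expected to hold fewer than 34 steps, the bound of its weakest 10% of peaks, and 34.0% after correction for the ratio in shared regions. The planned test took a share under 50% as evidence against depth, which was wrong: regions found in one replicate alone are selected for high values there, which lowers both shares by an amount not estimated. Depth therefore stays open as the source of most of them. Of these regions 8.52% touched stretches of replicate 1 at a false discovery rate of 0.05 or below.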
